A study of Homo sapiens with 6 samples.

How the data were processed

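Total RNA from CUTLL1 cells treated with DAPT (10 µM) or DMSO for 3 days was extracted with a microRNA kit and labelled with Cy3, per the labels, and hybridised to 1-colour Agilent human miRNA arrays. There were 2 groups of 3 arrays, grouped and numbered by their sample titles. Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.5.1.1 and hold linear intensity values per spot: a processed signal after background subtraction, a median signal, a local background and a total signal per miRNA, with flags for spots well above background, saturated or outlying. No normalization between arrays had been applied to these intensities. The value table the authors deposited for the series holds log2 values for 960 features, with the same 75th percentile (3.18) and maximum (16.9) in every column. Set against the log2 total signal per miRNA of the same array, they had slopes of 0.944 to 0.979 and correlations of 0.9987 to 0.9996 across miRNAs, which are not independent replicates, and each column matched its own array best. Its medians were 0.0096, 0.0532 and 0.0113 for DMSO replicates 1 to 3 and 0.0384, 0.0104 and 0.0113 for DAPT replicates 1 to 3. Its log2 scale was inferred from these slopes, and how it was centred and normalized is not given in the sources used here. The submitters' processing notes name RMA, affy, MAS5 and GCOS without a role, and no step is credited to them here.

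Control spots and spots with outlier flags were left out (6.0% to 7.5% of spots were population outliers), and spots of a probe were averaged on the linear scale. Probes were called detected on an array where more than a share of 0.5 of their spots were well above background. Each array's processed signals were divided by their 75th percentile over the 291 probes detected on all 6 arrays. These percentiles were 959, 795.6 and 615.5 for DMSO replicates 1 to 3 and 792.8, 1030 and 880.6 for DAPT replicates 1 to 3. Scaled signals were floored at 0.0269, or -5.22 on the log2 scale, the median over arrays of the 1st percentile (a quantile of 0.01) of spots well above background, and then taken to log2. The log2 values of a miRNA's detected probes were averaged. Human miRNAs with a probe detected on all 3 arrays of at least 1 group were tested. No tested miRNA was undetected on a whole group, but the floor limits the falls of miR-21* and miR-378*, whose DAPT values lie at or near it. Of the 23 miRNAs past the test, 22 had 2 or more detected probes, and in all 22 every such probe moved in the same direction. Names are those of the array design; a later comparison with the human gene table of assembly GRCh38.p14 matched 161 of 169 tested miRNAs to a gene.

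Differences (DAPT minus DMSO) were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with 4 residual degrees of freedom per miRNA, a prior of 4.04, no covariate, and Benjamini-Hochberg adjustment over the 169 miRNAs. The threshold was an adjusted p of 0.05. An exact permutation test of 3 against 3 arrays has only 10 distinct splits and so cannot give a p under 0.10; the limma p-values rest on its model. Lists of miRNAs were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, where at least 3 members were tested. Camera compares a list with all other miRNAs, while fry asks whether a list's own members move one way.

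Slide numbers and positions were read from the file headers. Arrays with the same replicate number shared a slide. By the correlation of deviations from the group means the numbers did not pair the arrays (-0.10, 0.15 and -0.05 across miRNAs for numbers 1 to 3), but as the slide is a batch that holds both groups, fits with the slide as a block are given as well, for each miRNA past the test and for the lists past camera, with within-slide values for the largest changes, miR-21 and the lists described by their median.

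The scripts were tested on data simulated from the real spots, in 10 simulations of this comparison that ran on 161 to 166 miRNAs, with 40 miRNAs changed in each. Of the changed miRNAs that passed the filter, 57.1% were recovered at 1.25-fold, 98.9% at 1.5-fold, 99.0% at 2-fold and 99.0% at 3-fold, and 1.18% of unchanged miRNAs were called. A list of 6 members raised by 1.5-fold passed camera in 10 of 10. Each simulated spot started from its mean over the 6 arrays, with noise drawn separately per miRNA and array. Slide effects and deviations shared across an array were not simulated, so these rates do not cover them.

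The groups, tests, lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. The rule named the 12 largest rises and 12 largest falls among miRNAs past the threshold with complete separation of the groups, miR-21 and miR-21*, up to 4 members of smallest p from each list, and the 5 brightest miRNAs. miR-923 and the 3 detected viral miRNAs were named after their values were seen. Alternatives covered the scaling, the background correction, the floor, the summary of probes, the filter, the block, the variance model, array weights, the deposited table and leaving out each array. The files hold no mean signal per spot, so normexp, planned on the mean signal, was run on the median signal and local background with an offset of 50. A maximum likelihood fit of normexp, normexp without an offset, plain subtraction of the local background and keeping population outlier spots were added after the data were seen. Chromosome positions are not given.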

Results

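MicroRNA levels were measured in CUTLL1 cells, an established line of T-cell acute lymphoblastic leukaemia that carries an activated Notch allele. Cells had been kept for 3 days either with 10 µM DAPT, a γ-secretase inhibitor that blocks the cleavage releasing the active intracellular part of Notch, or with the solvent DMSO alone. Each group held 3 arrays, described in the series record as biological replicates; nothing further was stated about how the cultures were separated, so p-values measure the spread between these samples. Every array carried 15024 non-control spots for 939 miRNAs, 851 of them human and 88 viral. Between 15.9% and 18.9% of the spots lay well above background, and 0 were saturated. Human miRNAs detected on an array numbered 205, 176 and 174 for DMSO replicates 1 to 3 and 172, 192 and 162 for DAPT replicates 1 to 3. The comparison covered 169 human miRNAs (19.9%) that were detected on all 3 arrays of at least 1 group. Of these, 160 were detected on all 6 arrays. The number of arrays limits the precision of every value.

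The comparison asked which miRNAs differ after Notch signalling is blocked in this leukaemia. Levels are log2 signals relative to the 75th percentile of the probes detected on every array, and changes are DAPT minus DMSO with n = 3 arrays per group. With DAPT, miR-149, which lies in an intron of the glypican gene GPC1, fell from -2.29 ± 0.09 (SD) to -3.95 ± 0.14, a 3.16-fold lower level (log2 change -1.66, SE 0.09, limma adjusted p = 1.36e-05). The lymphocyte miRNA miR-150, which accumulates as lymphocytes mature and targets MYB, rose from -2.85 ± 0.05 to -1.93 ± 0.03, 1.89-fold higher (0.92, SE 0.07, limma adjusted p = 5.54e-05). Both arms of the miR-9 hairpin, best known from neural differentiation, fell: miR-9 by 0.87 (SE 0.09) and miR-9* by 0.64 (SE 0.07), with limma adjusted p = 0.000436 and 0.000877. The level of miR-128, an miRNA of brain that is also high in lymphoblastic leukaemia, rose 1.52-fold (0.60, SE 0.07, limma adjusted p = 0.000877). The level of miR-29b, which targets DNA methyltransferases, fell by 0.52 (SE 0.06, limma adjusted p = 0.00101). The brightest human miRNA, the blood-cell marker miR-142-3p, was at 5.58 ± 0.06 in DMSO and 5.65 ± 0.08 with DAPT and did not pass (0.07, SE 0.07).

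Both arms of miR-21, an oncogenic miRNA that represses PDCD4, were lower with DAPT. The abundant arm miR-21 fell from 4.44 ± 0.03 to 4.12 ± 0.02, a change of -19.9% in signal (-0.32, SE 0.06, limma adjusted p = 0.0163), with changes of -0.31, -0.36 and -0.29 on the 3 slides. With the slide as a block its limma adjusted p was 0.0502, and in the values deposited by the submitters the change was 0.00, since miR-21 held rank 6 in every column of that table. Leaving out DAPT replicate 2 or 3 raised the limma adjusted p of miR-21 to 0.103 and 0.109. The passenger arm miR-21* fell by 0.72 (SE 0.12, limma adjusted p = 0.0071). It was detected on 3 of 3 DMSO arrays and 2 of 3 DAPT arrays, and 1 of its 2 probes lay at the floor on all 3 DAPT arrays, so the floor limits the fall given, which ran from -1.41 to 0 over the alternatives. Both arms also passed when adjusted over the list alone.

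In total 23 of 169 miRNAs passed limma at a Benjamini-Hochberg adjusted p under 0.05, of which 10 rose and 13 fell; 48 had an unadjusted p under 0.05. All 23 had 3 DAPT values on one side of the 3 DMSO values, which by itself gives the same sign on 3 of 3 slides. Such separation was found for 58 of the 169, where chance gives 10%. Only 6 of the 23 changed by 1.5-fold or more, and the median size of the 23 changes was 0.37. The other 8 rises, after those of miR-150 and miR-128, were between 0.29 and 0.46: miR-92a-1*, miR-181b, miR-454, miR-181a, miR-16, miR-26a, miR-15a and miR-181a*. Of these, miR-92a-1* and miR-454 turned negative after normexp, and with the slide as a block miR-92a-1*, miR-454, miR-26a, miR-15a and miR-181a* did not pass (limma adjusted p between 0.0540 and 0.0586). The remaining falls were those of miR-1274a, miR-342-3p, miR-378, miR-720, miR-378*, miR-1260 and miR-221, between -0.47 and -0.32, and with the slide as a block miR-378, miR-378*, miR-1260 and miR-221 did not pass (limma adjusted p between 0.0540 and 0.0582). The fall of miR-378* is limited by the floor, since it was detected on 1 of 3 DAPT arrays and its DAPT values lay between -5.22 and -5.15. The largest difference that did not pass was that of miR-494, at 1.03 with an SE of 0.41 (limma adjusted p = 0.142, or 0.0491 with the slide as a block). It varied between slides, at 1.54, 1.45 and 0.09 on slides 1 to 3.

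**Figure D1:**
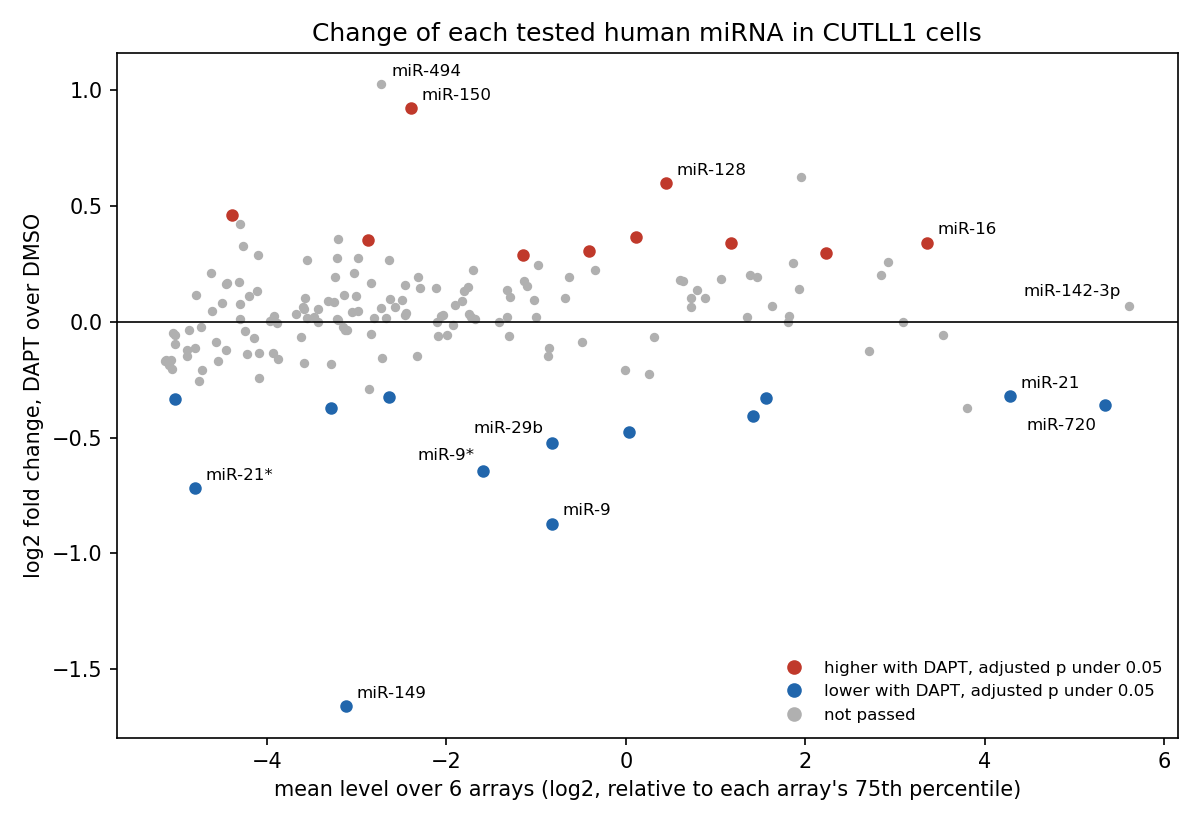
Each point is a tested human miRNA, with its mean log2 level over 6 arrays on the horizontal axis and its log2 fold change (DAPT over DMSO) on the vertical axis; coloured points passed the limma test. The 10 rises and 13 falls lie at low and high levels alike, with miR-149 lowest at -1.66 and miR-150 the highest of those that passed at 0.92.

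**Figure D2:**
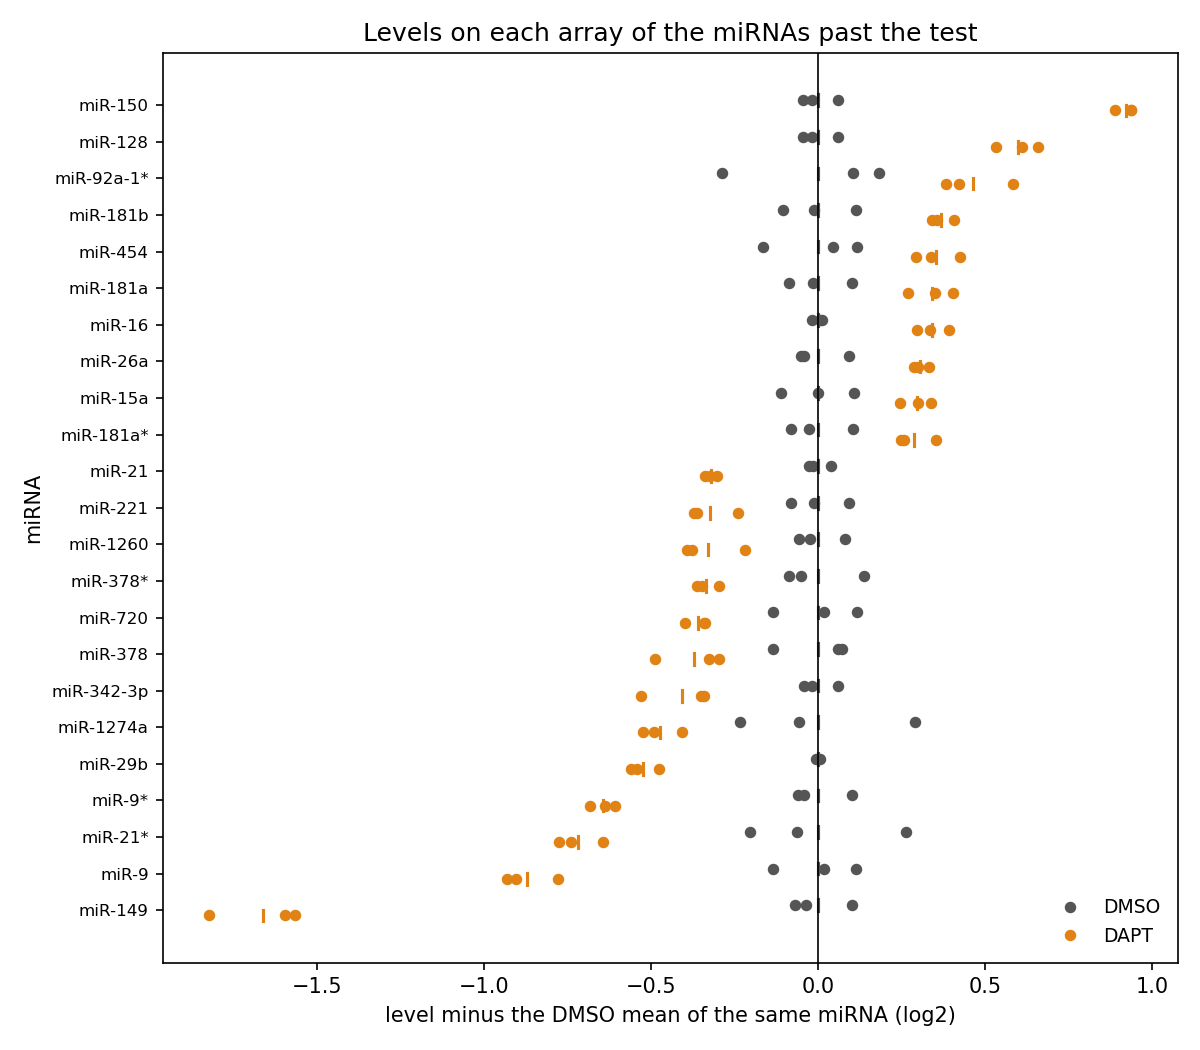
Points show the log2 level of each of the 23 miRNAs on every array, minus the mean of its 3 DMSO arrays, and short bars show group means. The 3 DAPT arrays (orange) lie on one side of the 3 DMSO arrays (grey) for all 23.

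Every slide held 1 DMSO and 1 DAPT array. With the slide as a block, 16 miRNAs passed (8 higher, 8 lower), and 13 of them were among the 23. With this block the limma adjusted p was between 1.72e-05 and 0.00611 for miR-149, miR-150, miR-9, miR-9*, miR-128, miR-29b and miR-21*, and between 0.0325 and 0.0491 for miR-342-3p, miR-16, miR-181b, miR-720, miR-181a and miR-1274a. Those changes that were largest kept their size within slides: miR-149 changed by -1.53, -1.79 and -1.67 on slides 1 to 3, miR-150 by 0.91, 0.98 and 0.88, and miR-9 by -0.80, -1.04 and -0.77. DMSO replicate 3 stood apart most from its group, with an SD of 0.26 (log2) from the mean of the other two; without it 40 miRNAs passed, the 23 included. Without DAPT replicate 2 the count was 9, and without DAPT replicate 3 it was 7. In all, 7 miRNAs passed whichever single array was left out: miR-149, miR-150, miR-9, miR-9*, miR-128, miR-29b and miR-21*. All DMSO arrays sat in the first row of their slide and all DAPT arrays in the second, so position on the slide and treatment cannot be told apart. The calls also depended on the signal used: 6 miRNAs passed when arrays were scaled over all probes, 5 without scaling and 0 after normexp background correction (limma, 9 at an unadjusted p under 0.05).

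The miRNAs were then grouped by 29 lists fixed beforehand, 21 of which had at least 3 tested members. With limma's camera and its preset correlation, 5 lists shifted at an adjusted p under 0.05. With an estimated correlation 0 did (2 at an unadjusted p under 0.05), and 5 passed fry, 4 of them the same lists. Lists share members, so their shifts are not all separate results. In particular, miR-15a, miR-15b, miR-16 and miR-195 are in both the miR-15/16 and the MYC-repressed lists.

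Of 6 tested members of the miR-181 family, which tunes T-cell receptor sensitivity in thymocytes, 3 rose (miR-181b by 0.37, miR-181a by 0.34 and miR-181a* by 0.29) and 3 did not pass, among them miR-181d at 0.36 (SE 0.11). With the slide as a block miR-181a* did not pass (limma adjusted p = 0.0586). Adjusted over the list alone, 6 of 6 passed. These are not 6 separate results, as miR-181a* and miR-181a-2* come from hairpins of miR-181a, with miR-181b close by. Likewise miR-181c lies close to miR-181d. The preset correlation takes all members as nearly independent. The list's median change was 0.32, with 0.32, 0.19 and 0.30 on slides 1 to 3. The list's camera adjusted p was 0.00734, or 0.0114 with the slide as a block, and adjusted p = 0.282 with an estimated correlation. Without scaling and with scaling over all probes it was 0.101 and 0.0987. After normexp, which moved the median of all miRNAs by -0.37, the list's median was -0.12 (camera adjusted p = 0.0413, as higher). As the normexp fits failed on DMSO replicate 3 and DAPT replicate 1, that pass does not support the list.

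Of 5 tested members of the miR-15/16 family, which represses BCL2 and G1 cyclins, miR-16 (0.34, SE 0.06) and miR-15a (0.30, SE 0.08) rose and 3 did not pass, among them miR-15b at 0.26 (SE 0.08) and miR-195 at 0.28 (SE 0.12). With the slide as a block miR-15a did not pass (limma adjusted p = 0.0586). With p-values adjusted over the list alone, 3 of 5 passed. The median change was 0.28, with 0.29, 0.19 and 0.31 on the 3 slides. The camera adjusted p was 0.0382, or 0.0408 with the slide as a block, and adjusted p = 0.356 with an estimated correlation. Without DMSO replicate 2, DMSO replicate 3 or DAPT replicate 2 it was 0.0633, 0.119 and 0.0679, and 0.222 without scaling and 0.196 with scaling over all probes.

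Of 28 tested members of the list of miRNAs reported to be repressed by MYC, itself a direct target of Notch in T-cell leukaemia, 4 rose (miR-150, miR-16, miR-26a and miR-15a), miR-29b fell and 23 did not pass; the counts adjusted over the list alone were the same, 4 and 1. The median change was 0.18, with 0.14, 0.12 and 0.22 on slides 1 to 3. After normexp, which moved the median of all miRNAs by -0.37, it was -0.06 (camera adjusted p = 0.00699, as higher). That pass does not support the list either, as the normexp fits failed on DMSO replicate 3 and DAPT replicate 1. The camera adjusted p was 0.00734, or 0.00796 with the slide as a block and 0.0844 without DMSO replicate 3, and adjusted p = 0.374 with an estimated correlation. It was 0.0542 without scaling, 0.061 with scaling over all probes and 0.0858 in the deposited values. Within this list, miR-26a, which represses EZH2, rose by 0.31 (SE 0.07), but with the slide as a block miR-26a and miR-15a did not pass (limma adjusted p = 0.0582 and 0.0586). None of the 8 tested let-7 miRNAs passed limma (1 at an unadjusted p under 0.05, let-7e at 0.33 with an SE of 0.11); adjusted over the list alone 0 passed. Their median was 0.20, with -0.02, 0.17 and 0.44 on slides 1 to 3, and the camera adjusted p 0.126. This depended on single arrays: without DMSO replicate 3 the camera adjusted p was 0.882, while the let-7 list passed without DMSO replicate 1 or DAPT replicate 1.

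Of the markers of other cell types, 0 of the miRNAs listed for erythroid and myeloid cells, for fibroblasts, muscle and endothelium, or for embryonic stem cells were well above background on all arrays of a group. The list of epithelial, liver and neural miRNAs had 4 tested members, of which 2 fell, also adjusted over the list alone. These were miR-9 and miR-9*, described above; the epithelial miR-200c and miR-141 differed by -0.14 (SE 0.09) and -0.14 (SE 0.13) and did not pass. The list's median was -0.39, with -0.44, -0.38 and -0.56 on slides 1 to 3. This median lies between the arms of miR-9 and the epithelial miRNAs and describes neither, and no liver member was tested. As miR-9 and miR-9* are arms of 1 hairpin, which the preset correlation takes as nearly independent, the list's shift rests on that hairpin. The camera adjusted p was 0.00734, or 0.00796 with the slide as a block, and adjusted p = 0.282 with an estimated correlation.

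A list of array entries taken here as fragments of tRNA, rRNA or vault RNA had 8 tested members, of which 3 fell: miR-720 by 0.36 (SE 0.08), miR-1260 by 0.33 (SE 0.08) and miR-1274a by 0.47 (SE 0.13). The listed vault RNA entries, miR-886-3p and miR-886-5p, were not among the 8 tested. With the slide as a block miR-1260 did not pass (limma adjusted p = 0.0582). Adjusted over the list alone, 4 were lower and 1, miR-923 (0.62, SE 0.20, named after its value was seen), was higher. Over all miRNAs miR-923 did not pass (limma adjusted p = 0.0719), but it did with the slide as a block (0.0165). The median was -0.29, with -0.11, -0.35 and -0.41 on slides 1 to 3. The camera adjusted p was 0.0382, or 0.0668 with the slide as a block, and adjusted p = 0.741 with an estimated correlation; fry gave an adjusted p of 0.117. The camera value was 0.0652 without DMSO replicate 2, 0.103 without DAPT replicate 2 and 0.0618 without DAPT replicate 3, and it stayed under the threshold in 14 of 26 alternatives.

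**Figure D3:**
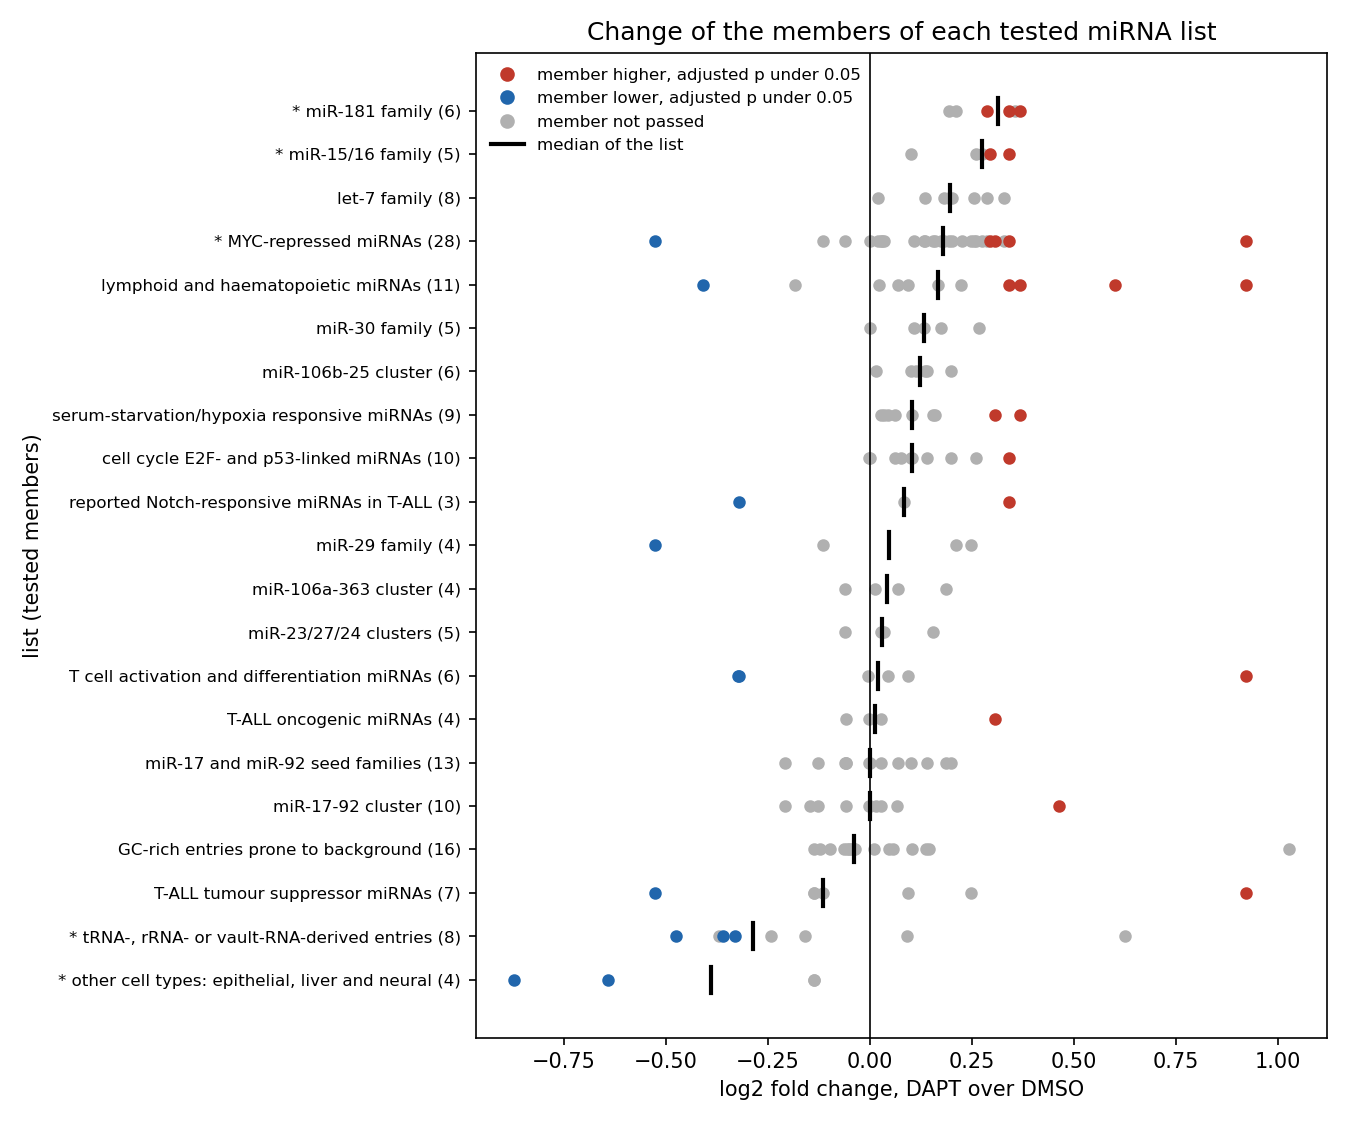
Points are the log2 fold changes (DAPT over DMSO) of the tested members of each list with at least 3 of them, coloured where the miRNA passed limma, with the number of tested members in brackets; black bars are list medians and asterisks mark camera with its preset correlation. Among these lists medians run from -0.39 for the epithelial, liver and neural list to 0.32 for the miR-181 family. With an estimated correlation the miR-181 family and the MYC list did not pass (camera adjusted p = 0.282 and 0.374). After normexp, which moved the median of all miRNAs by -0.37, the medians of both were below 0. The normexp fits failed on DMSO replicate 3 and DAPT replicate 1, so that both passed camera there as higher is no support.

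Among miRNAs of blood cells, the lymphoid and haematopoietic list had 11 tested members, of which 4 rose (miR-150, miR-128, miR-181b and miR-181a) and miR-342-3p, hosted by the EVL gene, fell by 0.41 (SE 0.08). Adjusted over the list alone, 5 were higher and 1 lower. The camera adjusted p was 0.0623, and adjusted p = 0.374 with an estimated correlation; fry gave an adjusted p of 0.0019. The median was 0.17, with 0.28, 0.17 and 0.20 on slides 1 to 3, and the camera adjusted p with the slide as a block was 0.0957. In the T-cell activation list, miR-150 rose, miR-21 and the CDKN1B-repressing miR-221 (-0.32, SE 0.08, block adjusted p = 0.0567) fell and 3 of 6 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.881). Of the 2 tested members of the cluster of miR-221 and miR-222, miR-222 differed by 0.00 (SE 0.08) and did not pass; 1 passed adjusted over the list alone. Of 3 tested miRNAs reported to respond to Notch in T-cell leukaemia, miR-181a rose, miR-21 fell and miR-148a differed by 0.08 (SE 0.06), with 2 of 3 passing adjusted over the list alone (camera adjusted p = 0.986).

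Of 7 tested tumour suppressor miRNAs of T-cell leukaemia, miR-150 rose, miR-29b fell and 5 did not pass; adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.9). Within the miR-29 family miR-29c differed by 0.25 (SE 0.08) and miR-29a by -0.11 (SE 0.09), or 0.09 without scaling. Neither passed over all miRNAs, although miR-29c did when adjusted over the list alone, where 1 was higher and 1 lower (camera adjusted p = 0.881). Of 4 tested oncogenic miRNAs of T-cell leukaemia miR-26a rose (block adjusted p = 0.0582), also adjusted over the list alone, while miR-19b, miR-92a and miR-20a differed by -0.06, 0.03 and 0.00, with SEs of 0.10, 0.07 and 0.08 (camera adjusted p = 0.881). The miR-26 family had 2 tested members, both passing adjusted over the list alone, with miR-26b at 0.23 (SE 0.09).

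The oncogenic cluster that runs from miR-17 to miR-92a in MIR17HG, a target of MYC, showed a median change of 0.00 over 10 tested members, with -0.02, 0.03 and -0.09 on slides 1 to 3; without scaling, where the median of all miRNAs moved up by 0.20, its median was above 0. Of these, 1 rose, the passenger arm miR-92a-1* (0.46, SE 0.13, block adjusted p = 0.0582); miR-18a was at -0.21 (SE 0.07) and 9 did not pass. Adjusted over the list alone, 0 passed (2 at an unadjusted limma p under 0.05), and the camera adjusted p was 0.816. In the related miR-106a-363 and miR-106b-25 clusters and the miR-17 and miR-92 seed families, 0 of 4, 0 of 6 and 0 of 13 tested members passed limma, over all miRNAs or adjusted over the list alone. At an unadjusted p under 0.05 there were 1, 1 and 3, and the camera adjusted p was 0.881, 0.269 and 0.999.

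Of the other lists, the E2F- and p53-linked list (10 tested) held 1 rise, miR-16, and the list of starvation and hypoxia miRNAs (9 tested) held 2, miR-181b and miR-26a, the latter with a block adjusted p of 0.0582. Adjusted over the list alone these counts were 1 and 2, and the camera adjusted p was 0.118 for both. In the miR-23/27/24 clusters (5 tested) and the miR-30 family (5 tested) 0 passed limma, with 1 each at an unadjusted p under 0.05 and a camera adjusted p of 0.9 and 0.26. Adjusted over the list alone these were 0 and 1, the latter miR-30e* at 0.27 (SE 0.08). Of 16 tested GC-rich entries prone to background 0 passed, also adjusted over the list alone, with miR-494 at an unadjusted p under 0.05 (camera adjusted p = 0.881). In the clusters around let-7e and let-7c 0 of 2 passed, and 1, let-7e, adjusted over the list alone. The miR-34 family had no tested member. Median, mean and camera direction differed in sign for the MIR17HG cluster, the miR-29 family, the T-cell activation list, the tumour suppressor list and the GC-rich entries, none of which passed.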

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

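Normexp fitted by maximum likelihood, normexp without an offset, subtraction of the local background without normexp and keeping population outlier spots were chosen after the data were seen; the other alternatives were planned. Of the 23 miRNAs, all 23 kept their direction, or a change of 0, in those of the 23 alternatives other than the 3 normexp ones that tested them (miR-21* and miR-378* were not tested with detection required on all arrays), and miR-149 and miR-150 passed in each of those. The 5 lists passed camera with its preset correlation in 23 (epithelial, liver and neural), 21 (miR-181), 19 (MYC-repressed), 18 (miR-15/16) and 14 (tRNA, rRNA and vault RNA) of these 23 alternatives. The first of these lists rests on the arms of the miR-9 hairpin. None of the 5 passed with an estimated correlation (camera adjusted p between 0.282 and 0.741). The estimates were -0.16 (epithelial, liver and neural), -0.12 (miR-15/16) and -0.02 (miR-181), all below the preset 0.01. They were 0.08 for the MYC-repressed list and 0.35 for the tRNA, rRNA and vault RNA list. Where the estimate lay below the preset value, correlation between members does not account for the loss.

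With scaling over all probes 6 miRNAs passed (2 higher, 4 lower) and 1 list. Without scaling 5 passed (4 higher, 1 lower) and 1 list, with all changes moved up by a median of 0.20. With the median of detected probes, 6 were higher and 17 lower; after quantile normalization 6 and 11; with the total gene signal 5 and 18. In the deposited values 9 were higher and 12 lower, and 3 lists passed. Without a filter on dim probes 7 of 851 passed (3 higher, 4 lower), where more miRNAs share the adjustment, and 11 lists. With detection required on all arrays 13 were higher and 11 lower, and with a floor 4 times higher 12 and 7. With trend and robust eBayes 17 were higher and 16 lower, with array weights 53 passed (35 and 18), and with outlier spots kept 30 (16 and 14). Subtracting the local background gave 19 (7 and 12) and 7 lists. A fold of at least 1.5 left 6, an adjusted p under 0.1 gave 39, and camera with an estimated correlation gave 0 lists (2 at an unadjusted p under 0.05; 5 by fry). Other than where stated, the cause was not tested.

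After normexp limma passed 0 miRNAs, 0 higher and 0 lower, with and without an offset and by maximum likelihood (9, 8 and 8 at an unadjusted p under 0.05), and 9 lists in each. The median change moved by -0.37, -0.41 and -0.38. miR-92a-1* turned to -0.45, -0.46 (without an offset) and -0.46 (maximum likelihood), and miR-454 to -0.27, -0.30 and -0.27. The fitted background means were -367.7 on DMSO replicate 3 and -55.05 on DAPT replicate 1 but between -3.38 and 11.1 on the other arrays, while the 5th percentile of the net signal was 4 and 10 on those 2, so the fits on them failed. Lists that passed after normexp are therefore no support. The oncogenic list of T-cell leukaemia and the miR-17 and miR-92 seed families passed in all 3 normexp alternatives but in 0 of the other 23.

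For the replicate block, in which the slide was a term, 16 miRNAs passed, 8 higher and 8 lower, and 4 lists, all among the 5.

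The fall of miR-21 kept its direction and lost its call with scaling over all probes (-0.39), after quantile normalization (-0.13), without scaling (-0.12), with the brightest probe (-0.29), with the replicate block (-0.32), after normexp with an offset (-0.22), without (-0.22) and by maximum likelihood (-0.19). It was 0 in the deposited values, where miR-21 has the same rank on all arrays. Its adjusted p ranged from 0.00228 to 1 over the alternatives.

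Leaving out each array in turn gave 7 to 40 miRNAs, 2 to 24 higher and 5 to 16 lower, 3 to 7 lists, and changes of miR-21 between -0.33 and -0.30. The count was 40 (24 higher, 16 lower) without DMSO replicate 3, 9 (3 and 6) without DAPT replicate 2 and 7 (2 and 5) without DAPT replicate 3. Without DMSO replicate 1 it was 19 (5 and 14), and without DMSO replicate 2 it was 16 (9 and 7). Lists fell to 3 without DMSO replicate 2, DMSO replicate 3 or DAPT replicate 2. Without DAPT replicates 2 or 3 miR-21 did not pass. For the other named miRNAs, 1369 values under alternatives kept direction and side of the threshold, 219 lost a call, 45 gained a call, 127 without a call changed sign and 6 with a call turned. Signal over background limits what could be tested, which was 19.9% of the 851 human miRNAs.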

Other observations

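Besides miR-142-3p, the brightest human entries were miR-720, miR-21, miR-1274b and the oncogenic miR-19b, and the difference of miR-1274b (-0.37, SE 0.12, limma adjusted p = 0.0719) did not pass. Of 88 viral miRNAs on the array, 3 were detected, all dim, the brightest at the 11.8th percentile of the tested human miRNAs. Their DMSO levels, -4.56, -5.04 and -4.58, were close to those of miR-21* (-4.45) and miR-378* (-4.86). Whether the signal of these 3 viral miRNAs is specific was not tested. Named after their values were seen, they were BART13 of Epstein-Barr virus (-0.25, SE 0.08, limma adjusted p = 0.0709), H6-3p of herpes simplex virus 1 (-0.11, SE 0.12) and K12-3 of Kaposi sarcoma herpesvirus (0.00, SE 0.12), and none passed. The 7 control features detected on all arrays did not pass either, with limma adjusted p between 0.651 and 0.676. The bright corner control was higher with DAPT by 0.21, and the others were lower, by -0.36 to -0.13. Each had an SE of 0.30, so the controls cannot exclude shifts as large as most of the called changes.

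Changes with DAPT were also compared between arms of one hairpin. The arms miR-181a and miR-181a* rose by 0.34 and 0.29, although with the slide as a block miR-181a* did not pass (limma adjusted p = 0.0586). The arms of miR-9 both fell, but by different amounts (-0.87 and -0.64). Over 27 pairs from the same hairpin the mean absolute difference in log2 change was 0.15. It was 0.27 when changes were permuted over all tested miRNAs (one-sided permutation p = 8e-04). As miR-149, miR-494 and miR-150, with the largest changes, are in none of these pairs, the permuted value is raised. The p-value thus does not measure how alike arms are.

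The tests below on other splits of the arrays, on scaling, on position, on miR-29b and on a shared source of tRNA-type fragments, and the neighbour test without the miR-17 clusters, were chosen after the result was seen; the others were set down before.

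For the 23 miRNAs that passed, 4 of the falls (miR-149 at -1.46, miR-9 at -0.67, miR-21* at -0.61 and miR-9* at -0.44) lay over 2 SE below 0 and all 10 rises over 2 SE above 0 without scaling between arrays. One factor per array does not give both, so scaling is not the whole cause, most clearly for miR-149. Of these falls only miR-149 passed limma without scaling. The limma adjusted p was 0.062 for miR-9, 0.0992 for miR-21* and 0.275 for miR-9*. As changes moved up by a median of 0.20 without scaling, the rises alone are no evidence. The bar of 2 SE was set after the calls without scaling (4 higher, 1 lower) were seen. Without scaling most calls ended because the SE grew, as for miR-9 from -0.87 (SE 0.09) to -0.67 (SE 0.22). For the other 9 falls, between -0.32 and -0.12 without scaling, scaling stays open. In all 22 of the 22 called miRNAs with 2 or more detected probes the probes moved the same way, which argues against single failing probes. Of 10 splits of the 6 arrays into 3 and 3, 1, the real one, called 23, and the highest other called 0; 10 splits are too few for a share under 0.05. Array position on the slide also stays open and cannot be told apart from the treatment, because 0 slide rows held arrays of both groups.

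The fall of miR-29b beside its family members was weighed next. The change of miR-29b minus miR-29c was -0.77 (SE 0.09), with -0.78, -0.87 and -0.67 on slides 1 to 3, a gap that signal shared by cross-hybridisation between family members would narrow, though no value decides how much is shared. Both probes of miR-29b fell, the smaller fall being -0.43, which argues against a failing probe. The value of miR-29c stayed above 0 and that of miR-29b below 0 under every scaling tried, while that of miR-29a (-0.11) turned to 0.09 without scaling. As miR-29b shares primary transcripts with both, a candidate explanation is a difference in its processing or decay, which was not tested and stays open beside array position. As shared signal would narrow the gap of -0.77 (SE 0.09), these values argue against cross-hybridisation between miR-29b and miR-29c as its cause. How far shared signal changed its size stays open.

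The lower values in the list of entries taken as tRNA, rRNA or vault RNA fragments may reflect RNA quality or handling. Without DMSO replicate 3, the array farthest from its group, the list's median was still -0.18, so that array is not the whole cause. The rRNA-derived miR-923, named after its values were seen, differed by 0.625 (SE 0.20) in the other direction. It did not pass over all miRNAs in the main fit. With the slide as a block it did (limma adjusted p = 0.0165), and also without DMSO replicate 3 (0.77, limma adjusted p = 0.0257). As 1 of 8 entries, miR-923 leaves a source shared by all such fragments open. A change in tRNA fragments alone, biological or from handling, was not tested.

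A hypothesis set down beforehand was that miRNA genes lying close together share their change with DAPT, as parts of one transcript would. Over 90 pairs of neighbours with different numbers, within 10 kb of each other and covering 53 miRNAs, the mean absolute difference in log2 change was 0.146, against 0.268 for permuted changes (one-sided permutation p = 0.0014). Without the 3 miR-17 clusters, 25 pairs gave 0.128 (p = 0.0025 by permutation), while 20 pairs with the same number gave 0.23 (p = 0.367 by permutation). The limit given for the hairpin arms holds here too: miR-149, miR-494 and miR-150 are in none of these pairs, which raises the permuted value. The p-values thus do not measure how alike neighbours are. Whether changes arise at shared transcripts is not decided by this test. Neighbours may also be alike in level, which was not tested.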
